A study of Bos taurus with 4 samples.

How the data were processed

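Granulosa cell RNA from Holstein cows kept for commercial embryo production was measured on 4 two-colour oligonucleotide arrays, each comparing 1 pool from good donors with 1 pool from poor donors. The design text gives 94 cows, sampled after ovarian stimulation and coasting, an interval without gonadotrophin before follicle aspiration. Per the labels' protocols, RNA of the pools was extracted with a kit for small samples, amplified linearly over 2 rounds to antisense RNA and labelled with Cy3 and Cy5 by direct coupling of the dyes. Good-donor pools 1 and 2 were in Cy5 with poor-donor pools 5 and 6 in Cy3 on arrays 1 and 2, and poor-donor pools 7 and 8 were in Cy5 with good-donor pools 3 and 4 in Cy3 on arrays 3 and 4. The labels do not state which or how many cows entered each pool. Pools were taken as the replicates, and the number of arrays limits the precision. Because the fit holds a dye term, a p-value measures the spread between arrays of the same dye orientation. Differences between arrays 1 and 2 and arrays 3 and 4 go to the dye term and are not part of that spread.

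The files held 2 kinds of values. Scanner tables hold spot and local background intensity, as deposited, per scanner wavelength and without normalization, per the file headers. The second kind is a log2 ratio per probe that the authors deposited in the series matrix, and its normalization is not given in the sources used here. Set against the scanner values, the deposited log2 ratios correlated at 0.971 to 0.980 with the loess ratios described below, with slopes of 1.16 to 1.22. They had medians of 0.0005, 0.0002, 0.0026 and -9.92e-05 on arrays 1 to 4, and ran as poor over good on all 4 arrays. They served as an alternative.

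Each array held 45212 spots, of which 43794 were probes, 1418 were control spots and 153 of these controls were structural negative controls. The median spot intensity was corrected by the normexp method of limma with the local background and an offset of 50. Loess (span 0.3) was run within each array with control spots at weight 0, and the ratios of arrays 1 and 2 were then turned to poor over good. A probe counted as above background where its raw intensity exceeded the mean of the negative controls of that channel by 2 SD. The analysis kept 26181 probes (59.8%) that were above background in all 4 pools of at least 1 donor group. No named gene was below background in all pools of a donor group, so no fold is given as a bound. A single probe spot reached the scanner's ceiling and was kept.

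Gene names came from the platform's annotation, which pairs 21790 probes with 1 symbol each, none with several, and leaves 22004 unnamed here. Of these symbols 20068 were current in the ARS-UCD2.0 annotation, 1644 were updated through a synonym and 78 were kept as given. Among the kept probes 14673 had a symbol, for 10975 genes. A gene was represented by its probe of highest mean brightness. No coordinates are given, because the build behind the probes is not given in the sources used here.

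For each probe limma fitted the poor over good log2 ratio and a probe-specific dye term over the 4 arrays, which leaves 2 residual degrees of freedom, and eBayes added 2.51 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method at 0.05. A second, looser threshold was an unadjusted p under 0.05 with at least a 1.5-fold difference. The dye term equals the difference between the mean ratio of arrays 3 and 4 and that of arrays 1 and 2, divided by 2. It cannot be separated from differences between the pools of these array pairs. The arrays were 4 areas of a single slide, so slide was not a batch.

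Before the data were examined, 20 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took up to 12 genes higher and 12 lower in poor donors past the adjusted threshold with the same sign on all 4 arrays, filled from genes past the looser threshold with the same sign on all 4 arrays by smallest p. It added up to 3 genes of smallest p from each list, and FSHR, LHCGR, CYP19A1, STAR, INHBA, PGR, IGFBP5, FST and AMH in all cases. This gave 84 genes, of which 6 higher and 12 lower came from the filling step. Lists were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation and with fry beside it, and adjusted over the 20 lists. Means with SD are over the 4 arrays' ratios.

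The functions were tested on simulated ratios for the 26181 probes, with spread drawn from the fitted prior and 200 changed probes in each of 20 simulations. Past the adjusted threshold, 72.8% of the 2-fold changes and 95.8% of the 4-fold changes were recovered, with a mean of 9.2 false calls per simulation. Each simulated change was equal on all arrays, and the spread was that between arrays of the same dye orientation. Recovery of changes that vary between pools was not simulated, so these shares do not show which differences the data could miss. In the list test on 10975 genes, a list shifted by 0.25 on the log2 scale was called in 100% of 20 simulations with the preset correlation and in 0% with the estimated correlation. The simulated genes varied independently, so this does not show how the preset test behaves with correlated genes. The test with an estimated correlation missed every shifted list. Its lack of a call in the data therefore cannot tell a shifted list from an unshifted one. In the data the estimated correlation was 0.50 for cholesterol synthesis and uptake and 0.79 for cytosolic ribosomal proteins.

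Alternatives fixed beforehand were a fit without the dye term, no background correction, subtraction of the local background, median centring in place of loess, Aquantile normalization between arrays, no filter and a stricter filter, the series matrix values, array weights, a separate-channel fit, a trended robust prior, leaving out each array, and for lists the other tests and the mean over a gene's probes. For lists the trended prior was used without its robust part, which camera does not offer. With an array left out, the fit kept the dye term. The other array of its dye orientation then weighed as much as the 2 arrays of the opposite orientation together. A value given without an array is therefore not the plain mean of the arrays that remain. It reflects the raised weight of that other array as well as the removal. Added after the data were seen were mean spot intensities, dark corner spots as negative controls, normexp fitted to the negative controls, and loess with a span of 0.1. The work used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.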

Results

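The arrays compared granulosa cells, the somatic cells that line the follicle and support the oocyte, between cows that mostly gave oocytes able to develop into embryos (good donors) and cows that mostly did not (poor donors). The question was which transcripts differ between these donors. Each of the 4 arrays held 1 good-donor pool and 1 poor-donor pool, so that each donor group had 4 pools, and the dyes were exchanged between arrays 1 and 2 and arrays 3 and 4. Median probe intensities were 49 to 58 in Cy5 and 121 to 164 in Cy3, where the negative controls had medians of 38 to 44 and 91 to 124. Between 64.3% and 69.0% of the 43794 probes were above background in the poor-donor pools, and between 66.0% and 72.7% in the good-donor pools.

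No probe passed an adjusted p of 0.05 between poor and good donors in the limma fit with a dye term, and the smallest adjusted p was 0.822. At an unadjusted p under 0.05 there were 1560 of the 26181 tested probes, where 1309 would be reached by chance. Of these, 13 probes were at least 1.5-fold higher and 72 at least 1.5-fold lower in poor donors, and 9 and 37 of them had the same sign on all 4 arrays. In the simulated ratios a mean of 147.75 unchanged probes passed both limits, against 85 probes here, so this set is not larger than its simulated background. The genes named next come from this looser set and are given with their values, since none of them passed the adjusted threshold. The 95% interval of a probe's log2 difference extended to either side by a median of 0.21, which is 1.16-fold. Like the p-values, this interval leaves out differences between the dye orientations, which the dye term took up. The count of 0 calls was also found under every alternative that was run, including the separate-channel fit. The looser counts were larger without array 4, at 211 higher and 120 lower, and without array 2, at 82 and 210. Without array 1 there were 51 higher and 85 lower, and without array 3 there were 27 and 93.

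Among the 6 higher genes that the rule named, the widest difference was in LUM, which encodes lumican, a proteoglycan of the collagen matrix. Its ratio was 1.85 ± 1.25 on the log2 scale (SD, n = 4; adjusted p = 0.822), with 0.17 on array 1 and 2.65, 1.65 and 2.95 on arrays 2, 3 and 4. RAB38, a small GTPase of vesicle traffic, stood at 0.93 ± 0.33 and IGSF11, a cell adhesion molecule, at 0.80 ± 0.21. USP50 had 0.83 ± 0.71 and HMCN1, which encodes the matrix protein hemicentin, 0.63 ± 0.50. Both of these had ratios of at most 0.32 on arrays 1 and 2 and of at least 1.02 on arrays 3 and 4. The sixth gene, LOC782977, had 0.62 ± 0.58, and 0.35 without array 3. LUM had 1.23 without array 2.

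Among the 12 lower genes that the rule named, all with the same sign on all 4 arrays, PTP4A3, which encodes a protein tyrosine phosphatase, had the widest difference at -1.45 ± 1.06 (SD, n = 4; adjusted p = 0.822), with -2.66 on array 2 and -0.11 on array 4. The most even of these genes across arrays was PLA2G6, a calcium-independent phospholipase A2, at -0.72 ± 0.12. PACSIN1, an adaptor of endocytosis, stood at -0.76 ± 0.31, and its probe was above background in 3 of the 4 poor-donor pools. ABCA3, a lipid transporter, had -0.63 ± 0.21 and ABHD8 -0.83 ± 0.44. The receptors FGFR2, for fibroblast growth factors, and PIGR, for polymeric immunoglobulins, had -0.75 ± 0.70 and -0.71 ± 0.50. WWC1, a regulator of the Hippo pathway, was at -0.68 ± 0.45 and ZBTB21 at -0.68 ± 0.46, but a second ZBTB21 probe gave 0.11. The other genes were LOC783508 at -0.70 ± 0.36, PLAC9 at -0.59 ± 0.41 and the interferon-inducible family member IFI27L2 at -0.59 ± 0.26. FGFR2 had -1.76 on array 1, and its fitted difference was -0.46 without that array, where that of PLAC9 was -0.39. FGFR2 levels were lowest in pools 3, 5 and 7, as were those of OVGP1 and of 20 of 36 motile cilia genes.

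**Figure D1:**
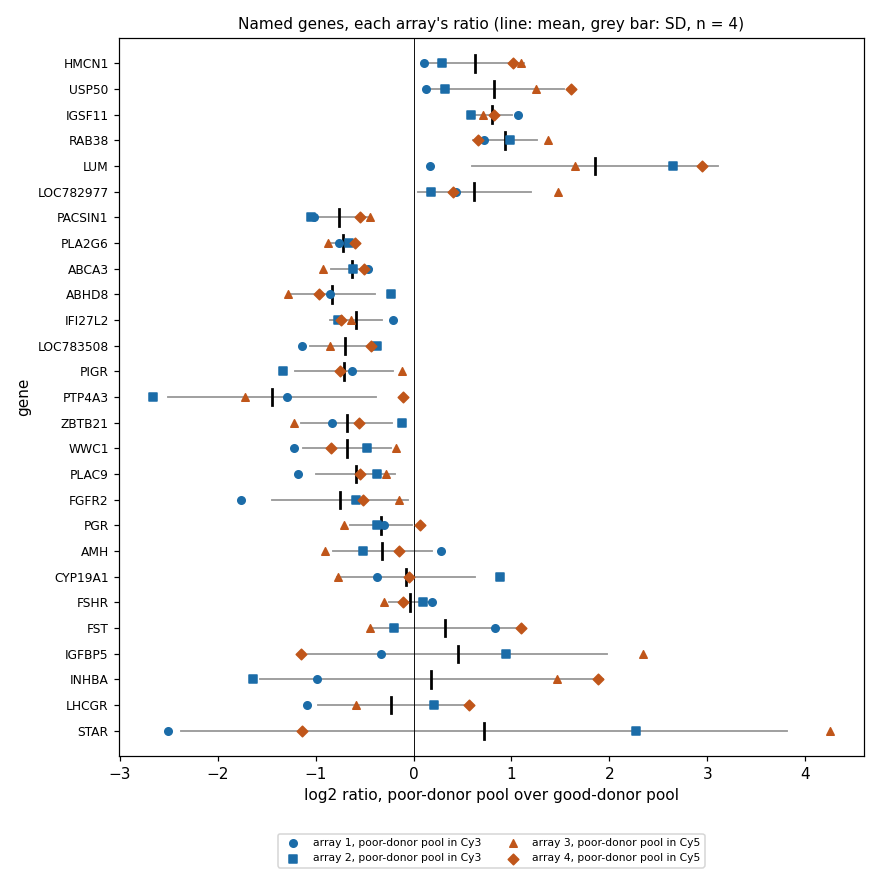
Log2 ratio of the poor-donor over the good-donor pool (horizontal axis) for 27 genes, with a point for each array, coloured by dye orientation, a line at the mean and a grey bar of 1 SD (n = 4). The upper 18 genes were chosen for having the same sign on all 4 arrays, while STAR, in the bottom row, ranges from -2.51 to 4.25.

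Cholesterol synthesis and uptake stood lower in poor donors as a list by camera (adjusted p = 0.00275), with 17 of 19 genes lower and a median of -0.21. The adjusted p was 0.982 with an estimated correlation between genes, which was 0.50, and 0.983 by fry. The test with an estimated correlation called 0% of the simulated shifted lists, so it cannot decide here or for the lists below. None of the genes passed when adjusted over the list alone. The members with the smallest p were DHCR7, the last enzyme of cholesterol synthesis, at -0.43 ± 0.41 (SD, n = 4), FDFT1, squalene synthase, at -0.45 ± 0.46, and SREBF2, the transcription factor that drives the pathway, at -0.29 ± 0.30. A second FDFT1 probe gave 0.001. The list means were -0.57 and -0.38 on arrays 1 and 3 and 0.08 and 0.02 on arrays 2 and 4. Leaving out an array raised the weight of the other array of its dye orientation. Without array 1 the list median was -0.03 (adjusted p = 0.35) and without array 3 it was -0.09 (adjusted p = 0.40), while it was -0.38 without array 2 and -0.37 without array 4. DHCR7 and FDFT1 had -0.18 and -0.17 without array 1, and SREBF2 had -0.13 without array 3.

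Hypoxia, glycolysis and angiogenesis stood higher in poor donors as a list by camera (adjusted p = 0.0197), with 17 of 23 genes higher and a median of 0.12. The adjusted p was 0.964 with an estimated correlation and 0.943 by fry. TPI1 and ENO1, enzymes of glycolysis, had 0.32 ± 0.29 and 0.29 ± 0.19, and ANGPT1, the ligand of the endothelial receptor TEK, had 0.31 ± 0.22 (SD, n = 4). A second ENO1 probe gave -0.21. None of the list's genes passed when adjusted over the list alone. The list median was 0.06 without array 2 (adjusted p = 0.174), 0.07 without array 3 (adjusted p = 0.259), 0.06 with median centring in place of loess (adjusted p = 0.0566) and 0.10 with mean spot intensities (adjusted p = 0.0985).

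Interferon response genes stood lower in poor donors as a list by camera (adjusted p = 0.00275), with 15 of 20 genes lower and a median of -0.08. The adjusted p was 0.964 with an estimated correlation, 0.650 by fry, 0.263 without the dye term and 0.238 without array 1. The median was -0.17 without array 2, -0.13 both with local background subtracted and with the series matrix values, and -0.04 with mean spot intensities. The list mean had opposite signs in the dye orientations, at 0.26 and 0.47 on arrays 1 and 2 and -0.58 and -0.71 on arrays 3 and 4. IFI27, an interferon-inducible mitochondrial protein, was at 0.71, 0.90, -2.46 and -2.70 on arrays 1 to 4, with a mean of -0.89 ± 1.96 (SD, n = 4). OAS1Z, of the oligoadenylate synthetase family, had a mean of -0.44 ± 1.66 and the antiviral GTPase MX1 -0.33 ± 0.98, each with the same change of sign. MX1 had -0.21 without array 4. Adjusted over the list alone 1 gene passed, IFI27 (adjusted p = 0.0037), and over all probes 0. The p of IFI27 came from the fit with a dye term, whose coefficient of -1.69 took up the change of sign. It therefore does not measure the full spread of IFI27 over the arrays.

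The lists of granulosa cell function did not pass. FSH-phase granulosa differentiation had 15 of 21 genes lower and a median of -0.08 (adjusted p = 0.155). Its member of smallest p was INHA, the inhibin alpha subunit, at -0.60 ± 1.32 (SD, n = 4), with -1.79 and -1.70 on arrays 1 and 2 and 0.40 and 0.68 on arrays 3 and 4. INHA was the 1 gene that passed when adjusted over the list alone (adjusted p = 0.0197), and 0 passed over all probes. This p came from the fit with a dye term, whose coefficient of 1.14 took up the change of sign between the array pairs. It therefore does not measure the full spread of INHA over the arrays. NR5A2, a nuclear receptor that drives steroidogenic genes, was at -0.25 ± 0.03, and its other 2 probes had the same sign. WT1, the transcription factor of early granulosa cells, was at -0.30 ± 0.33. WT1 had -0.19 without array 1. The list median was -0.13 with median centring in place of loess (adjusted p = 0.0487) and -0.19 without array 4 (adjusted p = 0.0123). With an estimated correlation the adjusted p was 0.970 and 0.992 in these, and 0.964 on all arrays. The median was 0.02 without array 3 (adjusted p = 0.862), -0.13 without array 2, -0.05 with the stricter filter on dim probes and -0.03 with mean spot intensities.

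Steroidogenesis had 9 of 17 genes lower and a median of -0.004 (adjusted p = 0.810). POR, an electron donor of some steroidogenic cytochromes, was at -0.26 ± 0.18 and NR0B1, a repressor of steroidogenic genes, at -0.14 ± 0.25. Among the named genes STAR, which brings cholesterol into mitochondria, differed most between arrays, with -2.51, 2.27, 4.25 and -1.14 on arrays 1 to 4 and a mean of 0.72 ± 3.09 (SD, n = 4). CYP19A1, the aromatase that makes oestradiol, had -0.08 ± 0.71. The gonadotrophin receptors FSHR and LHCGR had -0.03 ± 0.22 and -0.23 ± 0.75, with LHCGR above background in 3 of 4 poor-donor pools. INHBA, the inhibin and activin beta A subunit, was at 0.18 ± 1.75, with -0.99 and -1.64 on arrays 1 and 2 and 1.47 and 1.88 on arrays 3 and 4. The remaining genes chosen in advance were FST, an activin antagonist, at 0.32 ± 0.76, AMH, a product of growing follicles, at -0.32 ± 0.51 and IGFBP5, an IGF-binding protein, at 0.45 ± 1.53. The sign of CYP19A1, FSHR, LHCGR, FST, IGFBP5 and STAR changed when 1 or another array was left out. AMH had -0.12 without array 2 and -0.13 without array 3, INHBA 0.02 without array 1 and NR0B1 -0.09 without array 3.

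Ovulatory and LH-surge response genes had a median of -0.03 and a mean of 0.04 over 23 genes (adjusted p = 0.838). PGR, the progesterone receptor induced by the LH surge, was at -0.33 ± 0.32 (SD, n = 4), JUNB at -0.27 ± 0.36 and HSD11B1, which converts cortisone to cortisol, at -0.18 ± 0.15, where a second HSD11B1 probe gave 0.06. Atresia and apoptosis had 10 of 16 genes higher and a median of 0.03 (adjusted p = 0.890). CDKN1A, the cell cycle inhibitor p21, was at 0.48 ± 0.37 and higher on all 4 arrays, CLU, the chaperone clusterin, at 0.65 ± 0.89, and TXNIP, an inhibitor of thioredoxin, at -0.35 ± 0.53. Without array 3 CLU had 0.28 and PGR -0.14, and without array 1 JUNB had -0.14, HSD11B1 -0.09 and TXNIP -0.20. Cell cycle and mitosis had 23 of 31 genes higher and a median of 0.04 (adjusted p = 0.228). CDC20 was at 0.25 ± 0.39, PLK1 at 0.22 ± 0.15 and HMMR at 0.17 ± 0.17, the last above background in 2 of 4 good-donor pools. The list mean was 0.52 on array 2 and -0.27 on array 4.

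Of the metabolic and stress lists, fatty acid and lipid handling had a median of -0.002 over 22 genes (adjusted p = 0.871). Its members of smallest p were all lower, with SREBF1, the transcription factor of lipid synthesis, at -0.54 ± 0.40, FADS2, a desaturase, at -0.42 ± 0.35 and PPARD at -0.36 ± 0.39 (SD, n = 4). The insulin-like growth factor system had 10 of 14 genes lower and a median of -0.08 (adjusted p = 0.198), with PIK3R1, a PI3-kinase subunit, at -0.30 ± 0.13, IGF1R at -0.28 ± 0.30 and IGFBP3 at -0.24 ± 0.22. The list median was -0.12 without array 3 and -0.04 without array 4. Endoplasmic reticulum stress had a median of -0.003 (adjusted p = 0.972) and ATF4, a stress-induced transcription factor, at 0.33 ± 0.21. Its members XBP1 and CANX had -0.24 ± 0.37 and 0.22 ± 0.39. Oxidative stress defence had a median of 0.01 (adjusted p = 0.878), with the metallothionein MT2A at 0.46 ± 0.76, TXN2 at -0.28 ± 0.21 and PRDX6 at -0.25 ± 0.23. Only 1 of the other 5 TXN2 probes shared its sign. Cytosolic ribosomal proteins had a median of -0.02 (adjusted p = 0.890) and a list mean of -0.54 on array 2 against 0.03, 0.17 and 0.32 on the others. The member of smallest p was RPL13, at -0.24 ± 0.59. Without array 1 SREBF1 had -0.31, FADS2 -0.23, PPARD -0.22, IGFBP3 -0.13 and XBP1 -0.09. Without array 2 CANX had 0.08, MT2A 0.30 and RPL13 -0.15, and IGF1R had -0.16 without array 1 and without array 4.

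Markers of other cells gave no call either. Theca and stroma markers, of the cell layers around the granulosa cells, had 12 of 18 genes higher, a median of 0.08 and a mean of 0.23 (adjusted p = 0.228). This list holds LUM, and its collagens COL1A1 and COL3A1 had 0.46 ± 0.27 and 0.37 ± 0.33 (SD, n = 4), higher on all 4 arrays. The list mean was 0.35 and 0.57 on arrays 2 and 3 and 0.03 and -0.03 on arrays 1 and 4, and its median was 0.20 without array 4 (adjusted p = 0.0193, and 0.992 with an estimated correlation) and -0.02 without array 3 (adjusted p = 0.788). On all arrays its adjusted p was 0.964 with an estimated correlation. The median was 0.04 both with no filter on dim probes and with mean spot intensities, and 0.13 with the stricter filter. Extracellular matrix and its turnover had a median of 0.02 (adjusted p = 0.972), with LAMB2 at -0.33 ± 0.30, CD44 at -0.17 ± 0.13 and COL4A1 at 0.21 ± 0.42. Leukocyte markers had a median of -0.004 (adjusted p = 0.972), with list means of 0.48 on array 2 and -0.62 on array 3. The T cell gene CD3E was at -0.44 ± 0.41 and the macrophage genes AIF1 and CD163 at 0.16 ± 0.57 and 0.24 ± 0.50. Without array 3 CD3E had -0.20, COL3A1 0.19 and COL4A1 0.11, and without array 2 CD163 had 0.06.

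Inflammatory cytokines and acute phase genes had a median of -0.04 (adjusted p = 0.838), with the neutrophil protein S100A9 at -0.43 ± 0.44 and CXCL10 at 0.26 ± 0.82 (SD, n = 4). Without array 1 these had -0.21 and -0.000128. Red cell and platelet markers had a median of 0.08 over 8 genes (adjusted p = 0.810), endothelial markers -0.02 over 8 genes (adjusted p = 0.838) and oocyte and cumulus carry-over markers -0.05 over 5 genes (adjusted p = 0.824). The median of the red cell and platelet markers was 0.04 without array 1 and 0.02 without array 4. The oocyte gene BMP15 was at -0.08 ± 0.06. Mean log2 levels per pool were 6.63 to 6.88 for the endothelial list and 6.64 to 6.85 for the oocyte list. These are near the levels of OVGP1 in pools 3, 5 and 7 (6.45 to 6.76), so a drop could be missed. In 3 lists the median, the mean and the test differed in sign. For the ovulatory list the median and the test were lower and the mean was higher. For the leukocyte markers the median and mean were below 0 and the test higher, and for extracellular matrix both were above 0 and the test lower.

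Leaving out an array brought further lists past the threshold by camera with the preset correlation. With an estimated one 0 passed, where the smallest adjusted p was 0.854 with 1 residual degree of freedom. That test also called 0% of the simulated shifted lists, so it cannot decide here. In these fits the other array of the same dye orientation gained weight. Array 2, which gained weight without array 1, had list means of 0.52 for cell cycle and mitosis and -0.54 for cytosolic ribosomal proteins. Without array 1, cell cycle and mitosis stood higher (median 0.19, adjusted p = 7.79e-06) and cytosolic ribosomal proteins lower (median -0.15, adjusted p = 3.76e-05). Without array 2 the ribosomal proteins instead stood higher (median 0.13, adjusted p = 0.000766), and steroidogenesis and the ovulatory genes stood lower, each with a median of -0.13 and an adjusted p of 0.0400. Without array 3 the insulin-like growth factor system stood lower and the leukocyte markers higher, each with an adjusted p of 0.0359. The leukocyte markers stood lower without array 4 (adjusted p = 0.0193). On all arrays these 6 lists had an adjusted p of 0.964 or 0.982 with an estimated correlation. The median of 14 of the 20 lists changed sign when 1 or another array was left out. Of the 84 named genes 8 changed sign and 38 others moved by over 1.5 times, and where a single value without an array is given for a gene above, it is the one nearest 0.

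**Figure D2:**
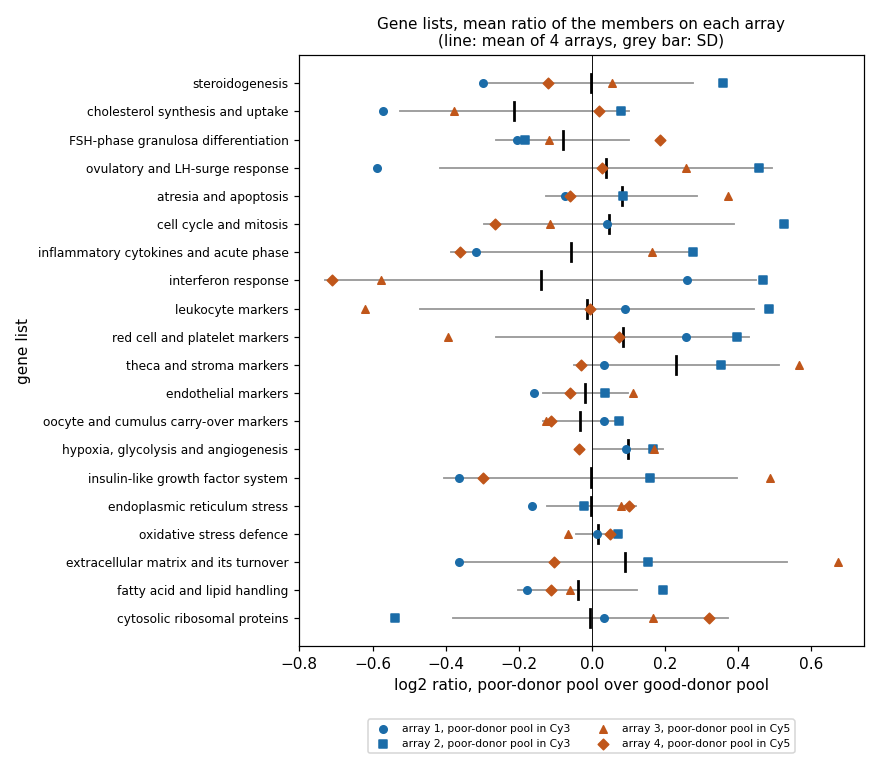
Mean log2 ratio of the poor-donor over the good-donor pool (horizontal axis) over the measured members of each of the 20 gene lists, with a point for each array, a line at the mean of the 4 arrays and a grey bar of 1 SD. The interferon response points lie at 0.26 and 0.47 for arrays 1 and 2 and at -0.58 and -0.71 for arrays 3 and 4.

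The poor over good ratios correlated weakly between arrays. Across the 26181 probes, which are not independent replicates, the ratios of arrays of the same dye orientation correlated at 0.01 (arrays 1 and 2) and 0.12 (arrays 3 and 4). Between orientations the correlations were -0.19, 0.01, -0.02 and -0.24. The ratio had the same sign on all 4 arrays in 11.4% of the probes, where independent signs would give 12.5%. The median SD of a probe's ratio over the arrays was 0.20, and the median absolute log2 difference between donor groups was 0.07.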

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

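The comparison with lists matched on brightness and the count of pool pairs were chosen after the interferon result was seen, and the count of lists under other assignments of the pools after the list calls were. Of 104 named genes and list means checked, 2 had an array far from the other 3, where chance gives about 5.2. NR5A2 had -0.30 on array 2 and about -0.24 on the others. IGFBP3 had -0.58 on array 1 and about -0.13 on the others.

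The dye coefficient tests whether the poor over good difference was unlike in the dye orientations, and a negative value means lower ratios on arrays 3 and 4. Adjusted over the named genes it passed 0.05 for 11 genes, while over all probes it passed for 0 (3204 at an unadjusted p under 0.05). Apart from those taken in all cases, the named genes were chosen by small p in the same fit. That choice favours a small residual spread, which the dye test shares, so the count of 11 is not a fair test. Negative coefficients were found for IFI27 (-1.69), OAS1Z (-1.43), MX1 (-0.83), the platelet gene GP9 (-0.59), AIF1 (-0.49) and CDC20 (-0.34). Positive ones were found for INHBA (1.49), INHA (1.14), USP50 (0.60), RPL13 (0.50) and HMCN1 (0.43). By camera with the preset correlation, the lists interferon response (mean -0.50, adjusted p = 5.93e-12), cell cycle and mitosis (mean -0.24, adjusted p = 1.94e-07), leukocyte markers (mean -0.30, adjusted p = 0.000657) and cytosolic ribosomal proteins (mean 0.25, adjusted p = 1.46e-05) differed between orientations. With an estimated correlation, a test that missed the simulated shifted lists, the adjusted p was 0.860 for each of these 4 lists. Probes with a mean brightness over 14, which include INHA, INHBA and RPL13, kept a median red over green log2 ratio of 0.20, 0.61, 0.31 and 0.46 on arrays 1 to 4 after loess.

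Interferon genes were brighter in Cy3 on all 4 arrays, that is in poor-donor pools 5 and 6 and good-donor pools 3 and 4. A leftover trend of the ratio with brightness is argued against, since the list's mean dye coefficient lay at percentile 0 of 10000 random lists matched on brightness, whose central 95% ran from -0.07 to 0.09. A dye bias of single probes is argued against by a second list of interferon-stimulated genes, written down before its values were seen, whose median over 24 genes was -0.14, against -0.06 to 0.09 in matched random lists. A difference between the pools, such as a higher interferon response in pools 3 to 6, may explain the pattern, as may a dye effect shared by these genes. These cannot be told apart, because 0 pool pairs were hybridised in both orientations.

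For the looser count of 85 probes, the 2 pools of each array can be assigned to the donor groups in 7 ways that leave the dye term estimable. Of these 5, the real one included, gave at least as many probes, with 302 as the highest of the others, and 7 splits are too few for a share under 0.05. At an unadjusted p under 0.05 alone the real assignment had 1560 probes, and the others had 863 to 2349, the last with the pools of array 2 exchanged. The real assignment called 3 gene lists by camera with the preset correlation, and 6 of the 7 assignments, the real one included, called at least as many, with 6 as the highest of the others.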

How the results depend on the processing

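Mean spot intensities, dark corner spots as negative controls, normexp on the negative controls, the loess of shorter span and the estimated correlation in combination with other alternatives were chosen after seeing the data. No probe passed the adjusted threshold under any alternative, and where the results below changed the cause was not tested. The 13 higher probes of the looser threshold became 21 without background correction, 31 with local background subtracted, 30 with the series matrix values, 20 in the separate-channel fit, 23 with normexp on negative controls and 5 with mean spot intensities. The 72 lower probes became 27 with mean spot intensities and stayed within 1.5 times under the other settings that use all 4 arrays. Leaving out each array gave 27 to 211 higher and 85 to 210 lower probes, with 1 residual degree of freedom. The 3 lists called became 0 with camera's estimated correlation and 0 by fry, and 3 to 6 when an array was left out. Cholesterol synthesis and uptake and interferon response were each called under 17 of 21 alternatives, and hypoxia, glycolysis and angiogenesis under 15. The mean correlation of arrays of the same dye orientation moved from 0.06 to 0.16 with median centring.

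Of the 84 named genes 74 kept their sign throughout and 0 passed an adjusted p of 0.05. With mean spot intensities the sign changed for CD44 (0.0170), FSHR (0.0160), GP9 (-0.0176) and LHCGR (0.00829). Leaving out each array, the log2 difference ranged from -0.000128 to 0.52 for CXCL10, from -0.39 to 0.24 for CYP19A1, from -0.11 to 0.00688 for FIGLA, from -0.0796 to 0.0153 for FSHR, from -0.0661 to 0.71 for FST, from -0.42 to 1.32 for IGFBP5, from -0.55 to 0.10 for LHCGR and from -0.63 to 2.07 for STAR. Signal over background limits the dim probes, since the Cy5 thresholds of 42.7 to 49.3 lay close to the median probe intensities.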

Other observations

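The genes of this part were chosen after their values were seen, while the cilia and epithelial lists and the tests of their ratios on array 1 were written down before their values were. The count by order of pools was also chosen after the pattern was seen. Levels are log2 intensities per pool after loess and Aquantile normalization, which sets the arrays on a common brightness scale without removing every difference between them. The genes given first were among those with the largest SD of the ratio over the arrays. That choice favours genes whose ratio does not follow the donor groups. TIMP1, an inhibitor of matrix metalloproteinases, had poor over good ratios of -2.04, 2.66, 4.47 and -1.93 on arrays 1 to 4. STAR, the stress-responsive ANKRD1, the growth factor BMP2 and PDGFRA, a receptor of mesenchymal cells, had the same signs, with ANKRD1 at -1.32, 1.36, 5.08 and -1.18. STAR levels were 12.4 in good-donor pool 1 and 13.2 in poor-donor pool 7, against 8.50 to 10.8 in the other 6 pools. In pool 7 the keratins KRT8 and KRT18 were at 15.5 and 12.8, where the other pools had at most 13.96 and 10.02. On array 3, 22 genes were over 4-fold higher in the poor-donor pool with the other arrays within 0.75 on the log2 scale, against 0 such genes on arrays 1, 2 and 4.

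OVGP1, the oviduct-specific glycoprotein, and some genes of motile cilia were far lower in 3 pools than in the other 5. OVGP1 was between 9.88 and 12.4 in pools 1, 2, 4, 6 and 8, and at 6.74, 6.76 and 6.45 in pools 3, 5 and 7. DNAH9, an axonemal dynein, was at 9.41 to 10.4 in the first 5 of these and at 6.49, 6.56 and 6.58 in the others. CAPSL and ROPN1L were at 9.18 or more in the same 5 pools and at 6.86 or less in the other 3. Of 36 further motile cilia genes, 20 had their lowest 3 levels in pools 3, 5 and 7, against 3.21% of all 15214 named genes. Others did not, such as CCDC40 (8.64 to 9.14 over the pools) and DNAH11 (7.34 to 7.92), and CCDC113 was at 5.05 in pool 6. FOXJ1 (6.36 to 6.54) and STK33 (6.53 to 6.69) did not either. In every pool these were near the level that OVGP1 had in pools 3, 5 and 7, so a drop there could not be seen. FGFR2, among the lower genes of poor donors, had its lowest levels in the same pools, at 6.60, 6.83 and 6.45 against 7.96 to 8.64 in the others. Array 1 joined a pool of each kind, and 7 genes were over 4-fold lower in its poor-donor pool with the other arrays within 0.75, among them CCDC65, of the ciliary axoneme, and DNAAF6, an assembly factor of axonemal dyneins.

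Cells of a ciliated epithelium in good-donor pool 1 may be the source of the array 1 difference. A list of 53 other motile cilia genes, 36 of them on the array, had a median poor over good ratio of -0.41 on array 1, at percentile 0 of matched random lists, and of 0.23, 0.01 and 0.12 on arrays 2 to 4, at percentiles 100, 56.3 and 99.99. Its marker TPPP3 was at 8.49 in pool 1 and 6.66 in pool 5. Pool 1 did not stand alone, since TPPP3 was at 7.90 to 8.19 in pools 2, 4, 6 and 8. In pools 3 and 7 it was at 6.30 and 6.31. Of the 36 genes 14 were above background in all 7 pools other than pool 1. The median of an epithelial list on array 1 was -0.08, at percentile 13.2, over 17 genes, of which 11 were above background in all 7 other pools and several, such as ELF3, GRHL2, RAB25 and ST14, were at 6.75 or less in each pool. Its members EPCAM and MUC1 followed the cilia genes, with EPCAM at 9.67 to 10.4 in pools 1, 2, 4, 6 and 8 and 6.89, 8.52 and 7.39 in pools 3, 5 and 7, and MUC1 at 7.67 to 8.48 and 6.21, 7.00 and 6.59. The bright members KRT19 and SPINT2 did not, with KRT19 at 14.1 in pool 5 and 12.9 in pool 6, and SPINT2 at 10.8 in pool 5 and 10.1 in pool 6. On array 1 alone, CLDN4, WFDC2, KRT7, ESRP1 and SPINT2 had poor over good ratios of -0.92, -0.91, -0.53, -0.50 and -0.35. KRT19 had 0.05 there and MAL2 0.67. ESRP1 also had its lowest levels in pools 3, 5 and 7. The list median on array 1 was the value of the dim GRHL2, so it says little of the brighter members. Of the 17 genes 3 had their lowest 3 levels in pools 3, 5 and 7. A damaged area of the array is argued against, since the 7 cilia probes with ratios under -1 lay no closer together than random spots, at percentile 70.2. Whether other cells or the granulosa cells themselves carried these transcripts stays open.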
